A study of Drosophila melanogaster with 2 samples.

How the data were processed

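Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster at the white prepupa stage, the immobile stage that opens metamorphosis. The flies carried a transgene for the protein CG10631 fused to green fluorescent protein, and chromatin sheared by sonication was precipitated with an antibody against that tag, per the labels' descriptions. The labels name 2 biological replicates of a single group, numbered 2 and 3. No second condition was analysed here, so no differential test was made.

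The deposited files are peak lists on the assemblies dm6 and dm3, and 4 lists per build were used. Each replicate has a list of 30000 regions. A merged list of 30000 regions derives from both replicates and is labelled as peaks and background for the irreproducible discovery rate (IDR) comparison. A shorter list holds the regions that passed the IDR comparison of the replicates. These descriptions are those accompanying the lists. The signal of each region, in the peak caller's own units, is the authors' value per peak and was used only to rank and describe peaks within a list. The −log10 q-value deposited with each region was used only to describe the lists. The aligner, the caller, the filters and the IDR threshold are not given in the sources used here. Across the peaks found in both replicates the merged signal was 1.00 times the sum of the replicate signals (median; 5th to 95th percentile 0.943 to 1.09), so the signal rose with the data behind a list. Read depth per replicate is unknown, and intervals given for shares of peaks or genes cover counting error only. Untagged or input control data were not analysed here, so the region lists alone could not separate binding from other sources of precipitated DNA.

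The reference was the dm6 genome sequence with the BDGP6.54 gene annotation, whose arms contain all deposited dm6 coordinates, and all positions are 1-based dm6 positions. Transposable element annotations were left out, which left 13968 protein-coding genes. The annotation has no separate class of long noncoding RNA genes, so the ncRNA class stood for it. No dm3 sequence or annotation was used, and only counts were taken from the dm3 lists. A promoter was the interval within 500 bp of an annotated start site. Each summit was put in 1 class in the order promoter, 5' UTR, CDS, 3' UTR, other exon, intron and intergenic. A protein-coding gene was called bound when a summit of the IDR list lay in its promoter.

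Chance levels for shares of peaks came from 1000 circular shifts of all summits within the arm intervals spanned by the merged list, with a two-sided empirical p whose smallest possible value is 0.002. Replicates were compared through their N strongest regions, N being the number of IDR peaks, with an overlap of at least 1 bp. For the requirement of 50% reciprocal overlap, the chance level was approximated by the distance between summits. For each of 30 gene lists, a two-sided Fisher's exact test compared bound promoters with those of all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists, sample odds ratios and conditional 95% intervals. The X chromosome was compared with the autosomes by Fisher's exact test in place of the binomial test that had been planned. When peaks were shifted, a list's bound share was first divided by the share of all genes, and 10000 shifts were added after the data were seen because the smallest p of 1000 adjusts to 0.0599 for a single list. Known motifs, 20 in all, were searched on both strands within 100 bp of each summit and in a window of that size 500 bp away, and compared by the exact McNemar test. All 6-mers were compared in the same windows on arms 2L, 2R, 3L and 4. Those with an adjusted p under 0.05 and a ratio over 1.5 were retested on 3R and X. Passing the retest again required an adjusted p under 0.05 and a ratio over 1.5. Signals of promoter and other peaks were compared by a permutation test on ranks with 100000 resamples. Peaks and genes are not independent replicates, so these tests describe the lists, and only the 2 replicates measure biological spread. Wilson 95% intervals were used for shares.

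Genes named are CG10631, the genes nearest to the 20 strongest peaks, up to 4 members of each list with the strongest promoter peak, and the 5 strongest peaks over 2 kb from any start site. The lists, motifs, tests and main alternatives were fixed before the data were examined. The alternatives were other promoter and motif windows, the stronger part of the IDR list, each replicate's own strongest regions, other overlap rules, other controls and null models, and the dm3 lists. Leaving out a replicate meant using the 8399 strongest regions of the other. The list test was tested on simulated data with the odds of 100 lists raised 4-fold over 13968 genes, where it called 98% of them and 3% of unchanged lists at an unadjusted p under 0.05. Simulated members were random genes bound independently, and the simulated sizes did not reach the smallest and largest real lists (8 and 180 genes). These rates therefore need not hold for those lists or where members share promoters. The 6-mer test was run on 8399 pairs of real windows from beside the summits, randomly swapped, with a site planted in the first set. It called both 6-mers of the planted site and 0 others. Both sets were alike in base composition, so this does not measure false calls where summits and flanks differ in GC content. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.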

Results

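The occupancy of CG10631 fused to green fluorescent protein was profiled by ChIP-seq in whole white prepupae, in 2 biological replicates. The IDR list on dm6 held 8399 peaks with a median width of 440 bp, the width of 81.4% of them. Some peaks overlapped: merging left 7803 separate regions, and 10 peaks repeated the interval of another. Counts and shares below treat each of the 8399 entries as a peak. The authors' signal per peak had a median of 190 and ranged from 100.1 to 3942. These peaks were the 8399 regions of highest signal among the 30000 regions of the merged list. Signals below are the authors' values in the merged list, followed where given by the mean of the replicate lists ± SD (n = 2).

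Strong peaks lay at the same places in both replicates. The strongest peak of the merged list, at the CG14100 promoter, and the next peak, in an intron of ush near cbt, ranked 1 and 2 in both replicates. Of the 8399 strongest regions of replicate 2, 87.6% overlapped such a region of replicate 3, against a mean of 5.03% after circular shifts (two-sided circular permutation p = 0.002, the smallest possible). Spearman's rho of the signals over the overlapping regions was 0.864, a value across peaks, which are not independent replicates. Summits of overlapping regions were a median of 19 bp apart. Among the IDR peaks, 7305 (87.0%, 95% interval 86.2 to 87.7%) overlapped the 8399 strongest regions of both replicates, and 41 overlapped those of neither. The IDR list was chosen by comparing these same replicates, so this high share follows in part from that choice. The replicate 3 list used here held no region at 51 IDR peaks and the replicate 2 list none at 29, the strongest of these 2 groups at rank 225, so overlap values would be too low if regions are missing from these lists. The signals of the replicates differed by over 1.5-fold at 959 peaks (11.5%) after the median ratio had been removed.

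**Figure D1:**
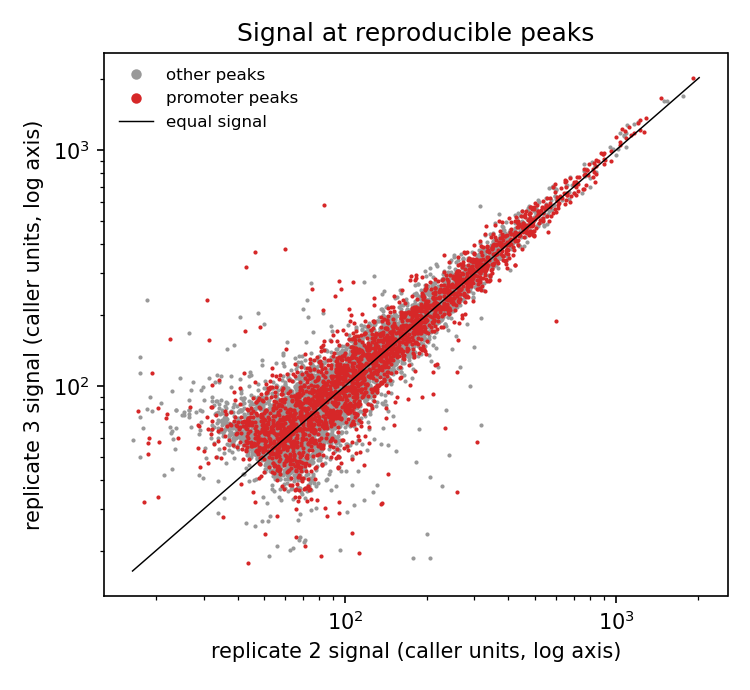
Signal in replicate 3 against replicate 2 (caller's units, both axes logarithmic) at the 8319 IDR peaks with an overlapping region in both replicates; each point is a peak, red at promoters and grey elsewhere, and the line marks equal signal. The points follow the line, with a median ratio of replicate 3 to replicate 2 of 1.05.

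Among the 20 strongest peaks, 12 had their summit in a promoter. The CG14100 peak (3L, 19590396 to 19590835) had its summit 91 bp from the start site and a signal of 3942 (1978 ± 70.8). Promoter peaks of similar rank lay at Ugalt, a UDP-galactose transporter gene (X, 2703691 to 2704091, signal 3119, 1567 ± 143), Tcs5 (3L, 5139311 to 5139692, 2642, 1326 ± 53.3) and Hsp27, a small heat shock protein gene (3L, 9383687 to 9384116, 2560, 1283 ± 79.3). The promoters of larp, mRpL41, CG8320, Art3, Chro, PNPase and CG18549 held further peaks of this group, with signals from 2221 at CG18549 to 2505 at larp. The peak nearest to Art3 also lay in the promoter of mRpS10. Intronic summits among the 20 lay in ush 1368 bp from the start site of cbt (2L, 480883 to 481301, signal 3518), in CG11050 (2L, 6612499 to 6612893, 3117), in Lk6 (3R, 11760849 to 11761257, 2497), in CG32772 (X, 4910079 to 4910698, 2370) and in CG4496 (2L, 7188380 to 7188832, 2273). A summit in osa (3R, 17704216 to 17704628, 2216) fell in the class of other exons. A pair of peaks on X had CG4004 as the nearest protein-coding gene, at 5006 and 6045 bp (12750840 to 12751640, signal 2542, in another exon, and 12752157 to 12752572, signal 2277, at the promoter of a gene that does not code for protein).

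Summits over 2 kb from any start site made up 44.9% of the list (3770 peaks). The strongest was intergenic on 2R (13035139 to 13035554), 11908 bp from the start site of CG13323, with a signal of 3125 (1574 ± 50.1). The next were intergenic near CG31668 (2L, 2202196 to 2202598, signal 2202, 1104 ± 102) and near CG43245 (3L, 10776359 to 10776748, 2199, 1107 ± 58.5). An intron of CG32486 (3L, 3060626 to 3060990, 1976, 993 ± 58.5) and an intron of CG12769 (2R, 8060826 to 8061218, 1975, 992 ± 22.9) held the remaining 2 of the 5.

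Promoters held 2621 summits, or 31.2% of the peaks (95% interval 30.2 to 32.2%), against 14.0% ± 0.584 (SD over shifts), a ratio of 2.23 (circular permutation test, adjusted p = 0.00233). Coding sequence held 10 summits, 0.119% against 14.1% after shifts, and 3' UTRs held 59, 0.702% against 4.58%. Introns held 3849 summits (45.8% against 38.9%) and intergenic sequence 1729 (20.6% against 26.8%), each with an adjusted p of 0.00233 in the circular permutation test. The share of 5' UTRs outside promoters was 0.429% against 0.806%, which turned to a ratio of 1.17 when exon classes were assigned before promoters. Other exons held 1.13% of summits against 0.835% (circular permutation test, adjusted p = 0.0120), a difference that did not pass the test among the 4199 strongest peaks (circular permutation test, adjusted p = 0.498). The promoter share was 49.1% among the 1000 strongest peaks (46.0 to 52.2%) and 21.8% among the 399 weakest (18.0 to 26.1%). Promoter peaks had a median signal of 225 and other peaks of 179 (permutation p = 1e-05, the smallest possible, across peaks).

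**Figure D2:**
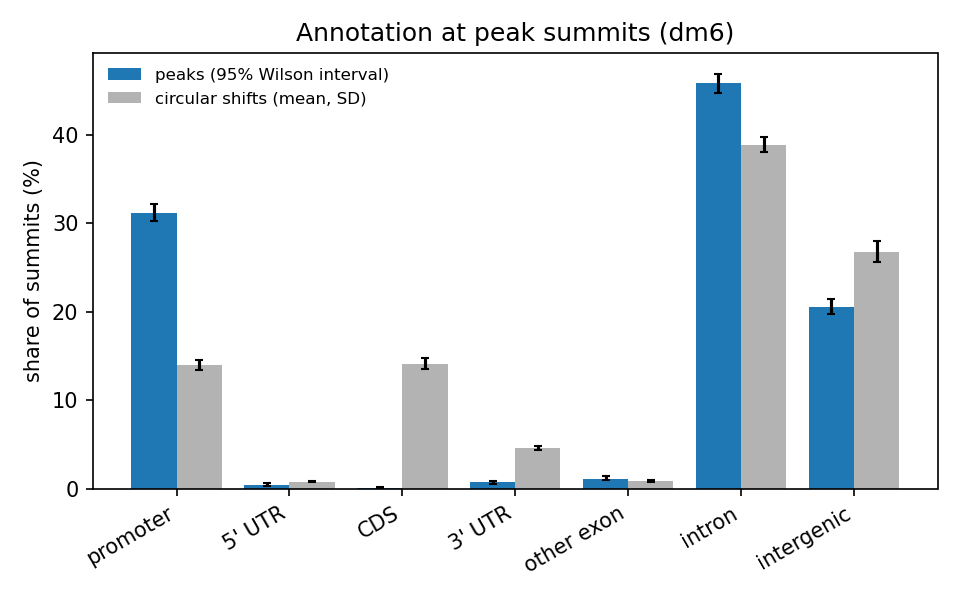
Share of the 8399 summits in each annotation class (blue bars, percent, with 95% Wilson intervals) beside the mean and SD of 1000 circular shifts (grey bars). Promoters held 31.2% of summits against 14.0%, and coding sequence held 0.119% against 14.1%.

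A total of 2712 of the 13968 protein-coding genes (19.4%) had a summit in a promoter, against 997 ± 45.0 genes (SD) after shifts. The summit lay upstream of the nearest start site at 88.8% of them, with quartiles at -258 and -94 bp. Bound promoters were more frequent than among other genes in 5 of the 30 lists. Core autophagy genes had 12 of 20 bound (odds ratio 6.25, 95% interval 2.35 to 17.6, Fisher's exact test, adjusted p = 0.000444). Among them, Atg17 (3R, 5669287 to 5669673) had a signal of 941 (472 ± 28.5), Atg2 (3L, 2773963 to 2774193) of 853 (428 ± 7.84), Atg18a of 658 and Atg4b of 552. Cytosolic ribosomal protein genes had 36 of 86 bound (odds ratio 3.02, 1.90 to 4.73, exact adjusted p = 1.58e-05), led by RpL34b (3R, 9401251 to 9401555, signal 766, 378 ± 25.5), RpL32 (609), RpS20 (544) and RpS27 (508). Mitochondrial ribosomal protein genes had 29 of 73 bound (odds ratio 2.75, 1.66 to 4.51, exact adjusted p = 0.000444), with stronger peaks at mRpL41 (2R, 15217569 to 15217956, signal 2451, 1234 ± 51.7), mRpS10 (2358), mRpS23 (2099) and mRpL23 (1866).

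Regulators of the response to the steroid hormone ecdysone had 9 of 20 bound (odds ratio 3.40, 1.25 to 9.04, exact adjusted p = 0.0335). The peak at Sox14, a transcription factor gene of this response, stood at 1617 (2R, 23978381 to 23978756, 817 ± 39.1), those at tai, Eip75B and Hr78 at 459, 448 and 408. The merged regions weaker than the IDR peaks gave the ecdysone regulators a higher odds ratio (4.80, 11 bound, exact adjusted p = 0.00977). Their enrichment was therefore not particular to the IDR peaks. Cell cycle and replication genes had 12 of 30 bound (odds ratio 2.77, 1.22 to 6.10, exact adjusted p = 0.0335), among them Dp (787), Mcm2 (532), aurA (407) and Cdk1 (296). Within strata of the number of start sites per gene, the ecdysone regulators (odds ratio 1.41, exact adjusted p = 0.579) and the cell cycle genes (2.24, exact adjusted p = 0.108) no longer passed. Neither list passed within 250 bp of a start site (3.21 and 2.55, exact adjusted p = 0.0585 and 0.0778) or with the 4199 strongest peaks (2.86 and 2.03, exact adjusted p = 0.125 and 0.278). The cell cycle genes also did not pass without replicate 2 (2.37, exact adjusted p = 0.0940) or within promoter GC quartiles (2.57, exact adjusted p = 0.0743). With 10000 shifts of the peaks as the null, cytosolic ribosomal proteins (circular permutation, adjusted p = 0.0360), chemoreceptors (0.00600, the smallest possible for a single list) and cuticle proteins (0.0330) passed. Shifted peaks bound fewer genes, and why lists did or did not pass under this null was not tested. In the same circular permutation test the other 5 lists called here did not pass. The ratio of their bound share to that after shifts, both relative to all genes, was 3.22 for autophagy (permutation, adjusted p = 0.0996), 2.40 for mitochondrial ribosomal proteins (0.0720), 1.95 for cell cycle genes (0.603), 1.20 for the ecdysone regulators (0.908) and 0.135 for testis genes (0.603).

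Bound promoters were rarer than among other genes in 3 lists. Odorant, gustatory and ionotropic receptors had 1 of 180 bound (odds ratio 0.0228, 0.000575 to 0.129, exact adjusted p = 2.22e-14), Gr77a with a signal of 218. This odds ratio was 0.0439 without replicate 3 (2 bound), 0.112 within 1000 bp of a start site (6 bound) and 0.0367 with the 4199 strongest peaks. Cuticle proteins had 2 of 122 (0.0685, 0.00820 to 0.253, exact adjusted p = 3.78e-08), Cpr12A at 133 and Cpr72Ea at 106, and the ratio was 0.102 without replicate 2, 0.0325 without replicate 3, 0.200 within 1000 bp (7 bound) and 0 with the 4199 strongest peaks. Genes of the spermatocyte programme and sperm had 1 of 47 (0.0899, 0.00223 to 0.527, exact adjusted p = 0.00354), Mst85C at 291. With the 4199 strongest peaks this last list did not pass (0.144, exact adjusted p = 0.113), and its ratio was 0 within 250 bp and 0.147 within 1000 bp.

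The other 22 lists did not pass the test. Polycomb and trithorax group genes had 9 of 25 bound (odds ratio 2.34, exact adjusted p = 0.132), with peaks at ph-p (signal 2214) and brm (1145). Aminoacyl-tRNA synthetases had 8 of 20 (2.77, exact adjusted p = 0.132), led by SerRS (977, with 512 in replicate 2 and no overlapping region in the replicate 3 list used here), IleRS (659) and GluProRS (628). Both lists passed within 250 bp of a start site (3.35 and 3.97, exact adjusted p = 0.0228 and 0.0196) and with 1 gene per shared promoter (3.17 and 3.89, exact adjusted p = 0.0196 and 0.0129). In the shared-promoter setting 10 and 9 members counted as bound, more than the 9 and 8 above. That setting therefore did not only drop genes, and its passes rest partly on added bound members. Insulator and promoter architecture genes had 6 of 16, with Chro at 2342 and M1BP at 666. Oxidative phosphorylation genes had 17 of 81 bound, led by ND-ASHI (953) and ND-MWFE (644), translation factors 10 of 51, led by eIF6 (1574) and eIF4EHP (1404), and the proteasome 7 of 48, led by Rpn5 (620). Heat shock genes had 6 of 18 bound, with Hsp26 at 739, and the near-identical Hsp70 copies in this list are uncertain because reads may map to several of them. Ecdysone effector genes had 4 of 19 (Ldh, 686), ecdysone synthesis and transport genes 3 of 12 (E23, 1259), clock genes 4 of 9 (cry, 554), the core spliceosome 5 of 17 (U2af50, 689) and fat body products 3 of 9 (Mtp, 288). Enhancer of split and Bearded genes had 3 of 15 bound (E(spl)m3-HLH, 803), apoptosis genes 2 of 12 (hid, 653), disc patterning genes 3 of 26 (so, 292), muscle genes 4 of 21 (sls, 413), Hox genes 1 of 8 (Dfd, 132) and neuronal genes 1 of 17 (elav, 898). No gene was bound among 11 salivary glue, 13 hemocyte, 14 antimicrobial peptide and 17 eggshell and yolk genes, with odds ratios that could reach 1.65, 1.36, 1.25 and 1.01 at the upper 95% limit. Without replicate 2, 1 hemocyte gene was bound (odds ratio 0.339).

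**Figure D3:**
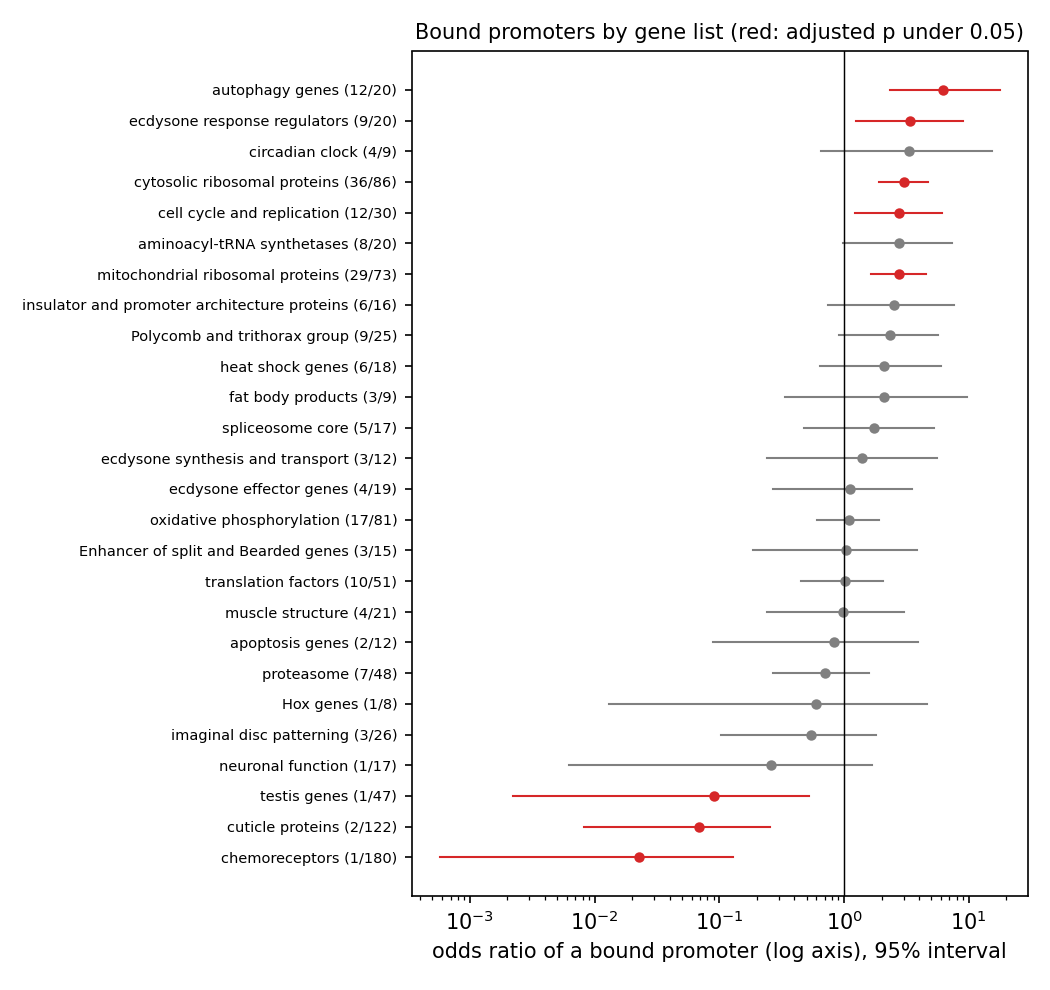
Odds ratio of a bound promoter (logarithmic axis, bars for 95% intervals) for each gene list with at least 1 bound member, with bound and total members in brackets; red marks an adjusted p under 0.05. Autophagy genes lie highest at 6.25 and chemoreceptors lowest at 0.0228.

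RNA gene classes were bound less often than the 19.4% of protein-coding genes. A protein-coding gene could count through any of its start sites, and no level after shifts is given here for RNA genes. These shares therefore do not show that RNA genes lack peaks relative to random positions. Summits lay within 500 bp of 16 of 290 tRNA genes (5.52%, odds ratio 0.242, Fisher's exact test, adjusted p = 3.09e-11) and at 11 of 269 snoRNA genes (4.09%, 0.177, exact adjusted p = 6.13e-13). The ncRNA class had 325 of 3289 bound (9.88%, 0.455, exact adjusted p = 1.04e-41). At snRNA genes, 3 of 32 were bound and the difference did not pass the test (0.429, exact p = 0.183). With the 4199 strongest peaks 0 snRNA genes were bound (exact adjusted p = 0.0173).

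On the X, 21.7% of protein-coding promoters were bound, against 19.0% on the autosomal arms 2L, 2R, 3L and 3R (odds ratio 1.19, 1.06 to 1.33, Fisher's exact test, p = 0.00326). The difference did not pass without replicate 3 (1.08, exact p = 0.164) and was 0.981 among the 4199 strongest peaks (exact p = 0.809). The X held 1601 peaks, or 69.7 per Mb, 3L held 1938, 3R 1917, 2L 1562 and 2R 1348, the last at 54.4 per Mb. These densities are per Mb of the arm interval spanned by the merged list, which is shorter than the whole arm. Chromosome 4 held 33 peaks and had 21 of 80 promoters bound (26.3%, 17.9 to 36.8%). The lists held 0 regions on Y.

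Summits lay in AT-rich DNA. Mean GC content within 100 bp of the summit was 33.7% ± 6.33 (SD over peaks), against 44.0% ± 8.22 in the flanks, a difference of -10.3 percentage points (95% interval -10.5 to -10.1) that stood at -11.4 in promoter peaks and -9.95 over 2 kb from any start site. The difference was -10.3 in the strongest regions of replicate 2 and -9.79 in those of replicate 3. Of 2080 6-mers, 307 were more frequent at summits on the discovery arms and 270 of these passed on 3R and X, led by sequences without G or C such as AATATA (41.8% of test windows against 17.1%). Against dinucleotide-shuffled windows 108 6-mers were more frequent, AATATA not among them, and 72 of these passed on 3R and X, led by CAGTGC (18.2% of test windows against 5.34%).

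**Figure D4:**
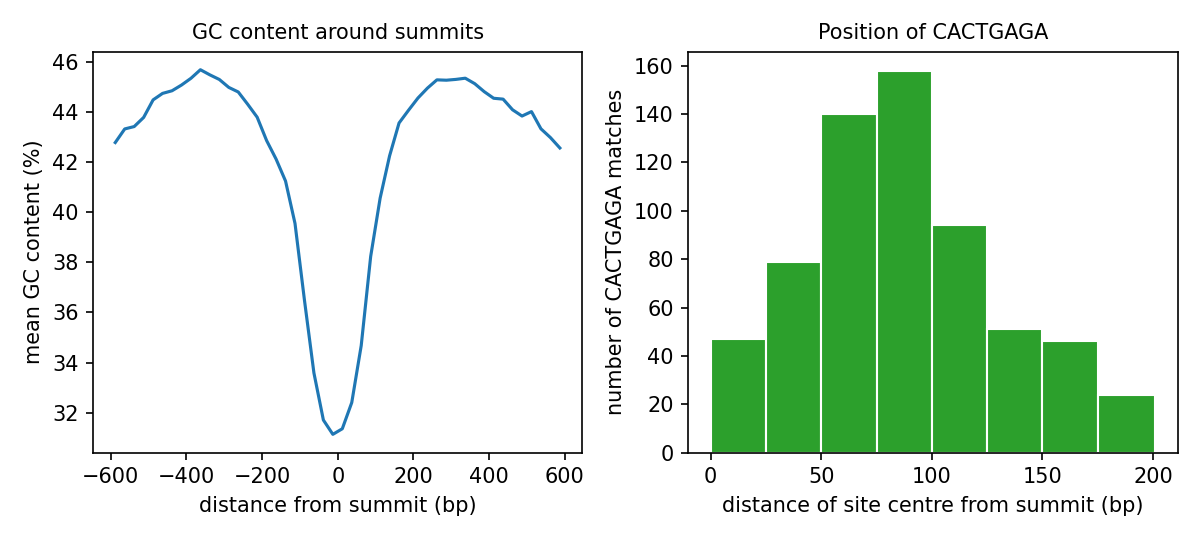
Left, mean GC content (percent) by distance from the summit in bp over the IDR peaks, which falls to 31.1% beside the summit. Right, number of matches of the sequence CACTGAGA by distance of their centre from the summit in bp, most frequent from 75 to 100 bp (158 matches).

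Among the known motifs, the TATA box TATAAA occurred at 40.3% of summits and 18.3% of flanks (ratio 2.21, exact McNemar test, adjusted p = 1.26e-213) and the GATA site at 39.9% and 27.3% (1.46, exact adjusted p = 1.44e-66). The DREF element TATCGATA, a motif of promoters of broadly expressed genes, was found at 1.71% and 0.345% (4.97, exact adjusted p = 4.48e-19). In promoter peaks it reached 4.69% against 0.610%, and outside promoters its ratio was 1.62 (exact adjusted p = 0.306). Higher ratios also held for the Ibf core (3.01), the Su(Hw) core (2.43), Ohler motif 1 (2.03), the A tract (1.49), Ohler motif 7 (1.41) and the BEAF-32 core (1.16). Lower ratios held for the Ftz-F1 site (0.247), the CA repeat (0.333), the GAGA element (0.507), the Zelda site (0.610), the E-boxes CAGCTG (0.613) and CACGTG (0.617), the Pho core (0.652) and the AP-1 site (0.704). Against dinucleotide-shuffled summit windows, the CA repeat, the GAGA element and CAGCTG were instead more frequent at summits (ratios 4.33, 3.79 and 2.34), and the GATA site less (0.892). Against the same windows the TATA box had a ratio of 1.10 (exact adjusted p = 1.02e-07), and the Ibf core (1.05), the Pho core (0.951), CACGTG (0.855) and the Zelda site (0.871) did not pass, with exact adjusted p from 0.0805 to 0.678. Ohler motif 1 did not pass among the 4199 strongest peaks (1.09, exact adjusted p = 0.932), nor did the Zelda site without replicate 2 or without replicate 3 (0.779 and 0.741, exact adjusted p = 0.159 and 0.102) or the AP-1 site without replicate 3 (0.843, exact adjusted p = 0.184) or within 50 bp (0.765, exact adjusted p = 0.134). In promoter peaks alone the Su(Hw) core, the GAGA element, CACGTG, the Zelda site and the AP-1 site did not pass (exact adjusted p from 0.0649 to 0.477). Outside promoters, Ohler motif 1 (1.83), the BEAF-32 core (1.03) and Ohler motif 7 (0.930) did not (exact adjusted p from 0.0634 to 0.537). The nuclear receptor element AGGTCA (0.948, exact adjusted p = 0.520), the CTCF core (1.43, exact adjusted p = 0.102) and the Pita core (exact adjusted p = 1) did not pass against flanks over all peaks. The CTCF core passed against shuffled windows (8.57, exact adjusted p = 3.79e-11) and without replicate 2 (2.32, exact adjusted p = 9.42e-05), but not without replicate 3 (1.04, exact adjusted p = 0.972) or in the 4199 strongest peaks (1.14, exact adjusted p = 0.851). AGGTCA was less frequent than in shuffled windows (0.750, exact adjusted p = 6.29e-05) and than in flanks among the 4199 strongest peaks (0.772, exact adjusted p = 0.0171).

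No region of the 4 dm6 lists overlapped CG10631 itself (2L, 19742817 to 19756904, minus strand). The nearest IDR peak (2L, 19764308 to 19764747) had its summit 7624 bp upstream of the gene, with a signal of 424 and rank 1378. It was found in both replicates, at ranks 1458 and 1319. The next lay 20120 bp downstream in an intron of Lar (2L, 19722477 to 19722916, signal 183, rank 4392).

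On the dm3 build the IDR list held 8356 peaks, against 8399 on dm6. The X held 1610 of them, 3L 1933, 3R 1892, 2L 1552, 2R 1329 and chromosome 4 held 34. Positions were not compared between the builds.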

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

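Both values come from data outside the comparisons of the report and were chosen after the data were seen. On dm3, 6 of the 8356 IDR peaks lay on scaffolds outside the main arms, as did 97 regions of the merged list and 120 and 96 of the replicate lists. The builds' scaffolds differ, so these counts were not compared with dm6. Among the 21601 regions of the merged list that were weaker than the IDR peaks, 1.91% (95% interval 1.74 to 2.10%) carried the sequence CACTGAGA within 100 bp of the summit, against 0.597% of flanks (exact McNemar p = 2.35e-36).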

How the results depend on the processing

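Of 577 alternative values for 76 results, 466 were labelled the same and 41 reversed, and the others weaker, stronger or moved. Tested values were the same if they kept their direction and side of the threshold. Untested ones were the same within their error or, for counts, within a wider margin. Bound promoters thus counted as the same although they fell from 2712 to 1823 with the 4199 strongest peaks. Reversed values changed direction, whether or not they passed a test. Settings with 10000 shifts for the lists, strata of start sites, the weaker merged regions and shuffled windows for 6-mers and 8-mers were chosen after the data were seen, and the cause of the changes below was not tested. Read depth is unknown, so its effect was not measured. Peaks backed by both replicates were 79.6% at 50% reciprocal overlap and 99.0% with all regions of each replicate. The 4199 strongest peaks gave 3 higher lists, without the ecdysone regulators and cell cycle genes, and 2 lower ones, without the testis genes, an X odds ratio of 0.981, other exons at a ratio of 1.14, an snRNA odds ratio of 0, and list odds ratios of 0.784 for ecdysone effectors, 0.888 for translation factors and 1.11 for muscle genes. With exon classes before promoters the 5' UTR ratio was 1.17. Without replicate 2 or replicate 3, odds ratios ranged from 1.08 to 1.21 for the X, from 0.794 to 1.36 for apoptosis genes, from 0.994 to 1.09 for translation factors and from 0.744 to 1.46 for ecdysone effectors. At 250 bp the ecdysone regulators and cell cycle genes no longer passed while Polycomb and trithorax genes (3.35) and aminoacyl-tRNA synthetases (3.97) did, and odds ratios were 0.424 for Enhancer of split and Bearded genes, 0.698 for ecdysone effectors, 0.742 for fat body products and 1.01 for the proteasome. At 1000 bp they were 1.10 for apoptosis, 1.75 for disc patterning, 1.03 for muscle and 0.910 for translation factors. With 1 gene per shared promoter, Polycomb and trithorax genes (3.17) and aminoacyl-tRNA synthetases (3.89) passed too, and muscle genes stood at 1.11. Bound members rose there to 10 for Polycomb and trithorax genes, 9 for aminoacyl-tRNA synthetases and 33 for mitochondrial ribosomal proteins. This setting was therefore not a plain check on the independence of genes. Shifts of the peaks as the null gave 0 higher and 0 lower lists when 1000 were drawn, where the smallest possible p adjusts to 0.0599 for a single list, so that this count was largely set by the number drawn, and ecdysone effectors stood at 0.938. With 10000 shifts there were 1 higher list, cytosolic ribosomal proteins, and 2 lower ones, chemoreceptors and cuticle proteins, and ecdysone effectors stood at 0.927. Strata of start sites gave 3 higher lists, 0.943 for ecdysone effectors and 0.926 for translation factors. The weaker merged regions gave 1 higher list, the ecdysone regulators (4.80, exact adjusted p = 0.00977), and 1 lower list, the chemoreceptors (0.458, exact adjusted p = 0.00977), and odds ratios of 0.349 for mitochondrial ribosomal proteins, 0.206 for aminoacyl-tRNA synthetases, 0 for ecdysone synthesis, 0.489 for each of clock, fat body and heat shock genes, 0.728 for translation factors, 0.889 for oxidative phosphorylation, 0.979 for Enhancer of split and Bearded genes, 1.20 for neuronal, 1.31 for Hox, 1.57 for muscle and 2.88 for disc patterning genes. Motifs called higher were 5 outside promoters, where Ohler motif 7 had a ratio of 0.930 and the element AGGTCA 1.04. This element had 1.01 within 50 bp. Motifs called lower were 4 in promoter peaks and 4 against shuffled windows, which gave 4.33 for the CA repeat, 2.34 for CAGCTG, 3.79 for the GAGA element and 0.892 for the GATA site. Shuffled windows gave 72 retested 6-mers and 449 8-mers in place of 270 6-mers. No paired analysis was possible because the design has a single group.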

Other observations

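The tests of 8-mers, of the site CACTGAGA, of strata of start sites and of the constitutive lists, and those of promoter GC for single lists, were chosen after the data were seen. With dinucleotide-shuffled summit windows as the control, which keep the base composition of the whole window, the leading 8-mer on the discovery arms was CACTGAGA. On 3R and X it occurred in 147 summit windows and 8 shuffled ones. The next 8-mers were TCAGTGCA, CAGTGCAC, AAATATAT, CTCAGTGC and CACTGTGC, several of which overlap its reverse complement TCTCAGTG. AAATATAT, without G or C, is unlike the site and occurred on 3R and X in 434 summit windows and 165 shuffled ones. The site lay within 100 bp of 4.66% of all summits against 0.441% of flanks, of 5.97% of summits outside promoters and of 1.76% of those in promoters. Within 200 bp it was found at 603 peaks, and its centre was a median of 83.0 bp from the summit.

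Summits lay mostly on the same side of this site. In 593 of 639 matches (92.8%, 95% interval 90.5 to 94.6%) the summit lay on the side after the last base of CACTGAGA, where mean GC content was 29.2% against 47.8% on the other side. Copies of a repeated element with the same surrounding sequence are argued against, since the surrounding 40 bp recurred at 5.01% of matches. Diverged copies would not be found this way, and transposable element annotations were not used. On the arms not used to find it, the site was 18.4 times as frequent as in shuffled windows, more than the base composition of the whole window gives. Shuffling does not keep the GC profile within a window, so an effect of composition local to the site is not excluded. A sequence-specific factor that binds beside an AT-rich stretch is a hypothesis that was not tested. Whether CG10631 itself reads the site was not tested either. The site adjoining AT-rich DNA throughout the genome stays open: at 2552 matches over 500 bp from every merged region the difference was -3.76 percentage points (95% interval -4.24 to -3.26), 20.2% of the -18.7 inside peaks, but the bound set for this share was wrong, since matches inside peaks were picked for a summit beside them, where DNA was AT-rich, and those outside for having no region near.

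The GC dip at summits may have technical sources. AT-rich start site regions as the source are argued against by the difference of -9.95 percentage points at summits over 2 kb from any start site. A preference of reads for AT-rich DNA stays open. Among windows of equal GC content promoters held a summit 2.88 times as often as other windows (95% interval 2.61 to 3.24), but the bound set for this ratio was wrong, since promoters can hold more summits on top of such a preference and the ratio does not bear on the dip. Open chromatin, and signal that any tagged protein would give, stay open because accessibility and untagged control data were not analysed here.

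The list differences could follow from general properties of promoters. Peaks at every constitutive promoter would give alike bound shares in 7 lists of cellular machinery if all their members were constitutive. The shares were unequal, from 14.6% for the proteasome to 41.9% for cytosolic ribosomal proteins (permutation p = 0.00143). Expression of the members was not checked. Members restricted to some tissues could also make the shares unequal, so this explanation stays open. Within strata of start site number, adjusted p was 0.000187 for autophagy, 0.00119 for cytosolic and 3.91e-06 for mitochondrial ribosomal proteins, while for the ecdysone regulators it was 0.579 with the odds ratio moving from 3.40 (1.25 to 9.04) to 1.41, which the number of start sites could account for, and for the cell cycle genes 0.108 with 2.77 (1.22 to 6.10) moving to 2.24, which stays open. Within promoter GC quartiles it was 0.000675 for autophagy, 1.41e-05 for cytosolic and 0.000608 for mitochondrial ribosomal proteins, 0.0188 for the ecdysone regulators and 0.0743 for the cell cycle genes, whose odds ratio moved little, from 2.77 to 2.57 (exact unadjusted p = 0.0198), which gives base composition no support there but does not exclude it. No biological explanation was tested, since the design has a single group.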
